A study of Arabidopsis thaliana with 4 samples.

How the data were processed

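Chromatin immunoprecipitation was combined with 2-colour arrays of genomic tiles in 1 group of samples, seedlings of Arabidopsis thaliana Col-0. Per the labels, 4 arrays compared IP and INPUT DNA of 2 replicates, and within each replicate the IP carried Cy5 on one array and Cy3 on the other. Per the labels' protocols, DNA was amplified and labelled directly with both dyes. The scanner, the background correction, the normalization and the genome build are not given in the sources used here.

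The deposited table of the whole series gives 1 value per spot and array, treated here as a score that is a log ratio of unstated base, since the values run from -3.36 to 3.002 and no source names the unit. The paired columns of each dye swap were identical in all 21743 spots with a value and both empty in the other 57. Identical columns cannot show whether the arrays were combined or the values of 1 array were entered for both. Of the empty spots, 39 had names of control type and 18 had tile names. Dye effects could not be assessed for this reason. From the values, most log ratios had 14 decimals, with 13 or fewer in 19.3% (replicate I) and 18.0% (replicate II) of tiles, against 10% for a random last digit.

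Values were turned in no column. The direction is called likely IP over INPUT, only from the longer upper tail, and counts are stated for the turned sign as well. Each replicate was centred on its median over tiles, with no loess or quantile step, because a mark can shift many tiles one way. The mean of the 2 replicates was tested against 0 per tile with limma 3.58.1 in R 4.3.3 (lmFit on an intercept, eBayes without trend or robust options), with Benjamini-Hochberg adjustment over tiles and a threshold of 0.05. There was 1 residual degree of freedom per tile, and the prior degrees of freedom were estimated at 21.7. The size rule asked for more than 1 above, or under -1 from, the median in both replicates. All limma p-values are two-sided.

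The table proved to hold a different kind of value from the one the design assumed. It gave 1 column of values per dye swap in place of separate arrays, and its tile names are plates and wells with no gene or position. The planned results on genes, gene lists, annotation classes, transposable element superfamilies, chromosomal domains and gene bodies were therefore not run. Gene names in the reference table (TAIR10.1) could not be joined to tile names and were not used here. Runs were taken over consecutive wells in the order of names, in place of genome order. The rule for named features, set before the data were examined, allowed at most 2 tiles per direction where no gene names are given: those with the highest and the lowest mean among called tiles with the same sign in both replicates. Plates, stretches of plates and runs were chosen after their values were seen.

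Results added after the data were seen were limma on plate medians and stretches of at least 5 consecutive plates with values, all called higher. The circular shift test of sets and of TC17 to TC30 was added too (all 21743 shifts, difference in mean rank, Benjamini-Hochberg over 6 tests). So were correlations between wells, stretches of at least 3 wells with a mean of at least 1.8, and single tiles at least 2 above both neighbours. Another addition was a comparison of interleaved grids of wells (odd or even rows by odd or even columns) within each plate. Runs of at least 2 called tiles were compared with 1000 shuffles of the tile order. Intervals of correlations are at the 95% level and treat pairs as independent, which neighbouring tiles are not.

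The tile test was tested on simulated data: 50 draws of 21743 tiles with the estimated spread, in each of which 200 tiles were changed by 0.5, 1 or 2. It found 0.57%, 46.4% and 99.96% of the changed tiles, with 45.0%, 13.7% and 12.8% of calls false on average. The prior degrees of freedom were estimated as infinite in 28, 20 and 27 of the draws, although the draws were made with 21.7. With n = 2, tile counts are for this reason less certain than the threshold implies. The draws had 200 changed tiles and independent noise, unlike the data, so the shares found and false do not carry over to the reported counts.

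Alternatives planned before the data were examined were no centring, centring on the mode, equal median absolute deviations, a trend with robust prior, a threshold of 0.01, a mixture of 2 normal components per replicate with a posterior of at least 0.99 in both, other top shares, and leaving out each replicate. Added later were centring on plate means, only sets TA and TB, removal of plate medians, leaving out the 3 stretches of plates, means in place of medians for plates and stretches, every setting applied to plates, stretches and next wells, and a reference of only the plates outside the stretches. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 (mixture) and matplotlib 3.10.9 were used for the other steps.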

Results

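The data describe H4K20me1, the monomethylated form of a lysine in the tail of histone H4, in seedlings of Arabidopsis thaliana ecotype Col-0. They belong to a project that set out to map chromatin marks across the genome of this plant. Seedlings were 10 days old and had grown in liquid medium at 22 °C under a 16 h photoperiod. DNA immunoprecipitated with an antibody against H4K20me1 (IP) was hybridised together with unselected chromatin DNA (INPUT) on 2-colour arrays of genomic tiles. There was 1 group with 2 replicates, I and II, and each replicate was hybridised on a pair of arrays with the dyes exchanged, which made 4 arrays. The labels do not say that the replicates were separate cultures, so p-values from limma measure only the spread between these samples, which may be technical. P-values from shifting or shuffling the order of tiles do not measure that spread.

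The table had 21800 spots, of which 21743 held a log ratio and 57 were empty. Both arrays of each dye swap held the same value for each of the 21743 tiles. Each replicate therefore gave 1 value per tile, and n = 2 throughout. Tiles were named by plate and well and fell into 5 sets: TA with 9328 tiles on 99 plates, TB with 9598 on 100, TC with 2405 on 27, TD with 96 on 1 and PD with 316 on 4. Gene names and genome positions of the tiles were not used here, so regions are given as plates and wells in the order of their names. The number of arrays limits the precision.

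The median deposited log ratio was -1.42 in replicate I (SD across tiles 0.618, range -3.36 to 3.002) and -1.15 in replicate II (SD 0.545, range -2.95 to 2.73). Values above 0 were held by 371 tiles (1.71%) in replicate I and 512 (2.35%) in replicate II. Neither the log base nor the channel in the numerator is stated for these values. The ratio is called likely IP over INPUT because its upper tail was the longer, by a rule set before the data were examined. Of 615 tiles more than 1 above the median in both replicates, 536 lay in 3 stretches of plates described below. The cause of their high values stays open, and if it is technical, that part of the tail does not bear on the direction. The top 1% of tiles began 1.54 and 1.35 above the median in replicates I and II, and the bottom 1% began 1.16 and 1.12 under it. With the sign turned, every count of higher tiles or plates becomes the count of lower ones and the reverse. Values in the rest of the text are minus the median of their replicate.

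The first comparison was of IP with INPUT over the regions of the array. Consecutive plates with high log ratios formed 3 stretches, which were picked on these same values. In TA21 to TA30 (886 tiles) the median was 0.485 in replicate I and 0.318 in replicate II, which lay 0.42 ± 0.124 (SD, n = 2) above that of all other tiles. In TA35 to TA51 (1544 tiles) the medians were 0.755 and 0.532, a difference of 0.68 ± 0.166 (SD, n = 2). In TC17 to TC30 (1123 tiles) they were 0.942 and 0.713, a difference of 0.86 ± 0.168 (SD, n = 2). These 40 plates held 3553 tiles (16.3%) and 1413 of the 1792 tiles called higher (78.9%). TC00 to TC13, the other part of set TC, had medians of -0.259 and -0.174.

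The highest single plates were TC17 at 1.39 ± 0.158 and TC29 at 1.34 ± 0.136 (SD, n = 2, limma adjusted p = 0.0003332 for each), followed among the TA plates by TA43 at 0.98 ± 0.162 (limma adjusted p = 0.0009672). Outside the 3 stretches the highest were TA57 at 0.43 ± 0.0436 and TB25 at 0.42 ± 0.0031 (limma adjusted p = 0.00379 for each), then TA62 at 0.35 ± 0.131 (limma adjusted p = 0.01618) and TA01 at 0.30 ± 0.072 (limma adjusted p = 0.01734). Of 231 plates, limma on plate medians called 53 higher and 59 lower than the median of all tiles, at an adjusted p of at most 0.05. The counts moved with the setting. At an adjusted p of at most 0.01 limma called 0 plates lower (78 at an unadjusted p under 0.05) and 33 higher, and centring on the mode of each replicate gave 10 lower. Equal median absolute deviations gave 100 lower, a trend with robust prior gave 98, and values without centring gave 228 lower and 0 higher (limma, also 0 higher at an unadjusted p under 0.05).

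**Figure D1:**
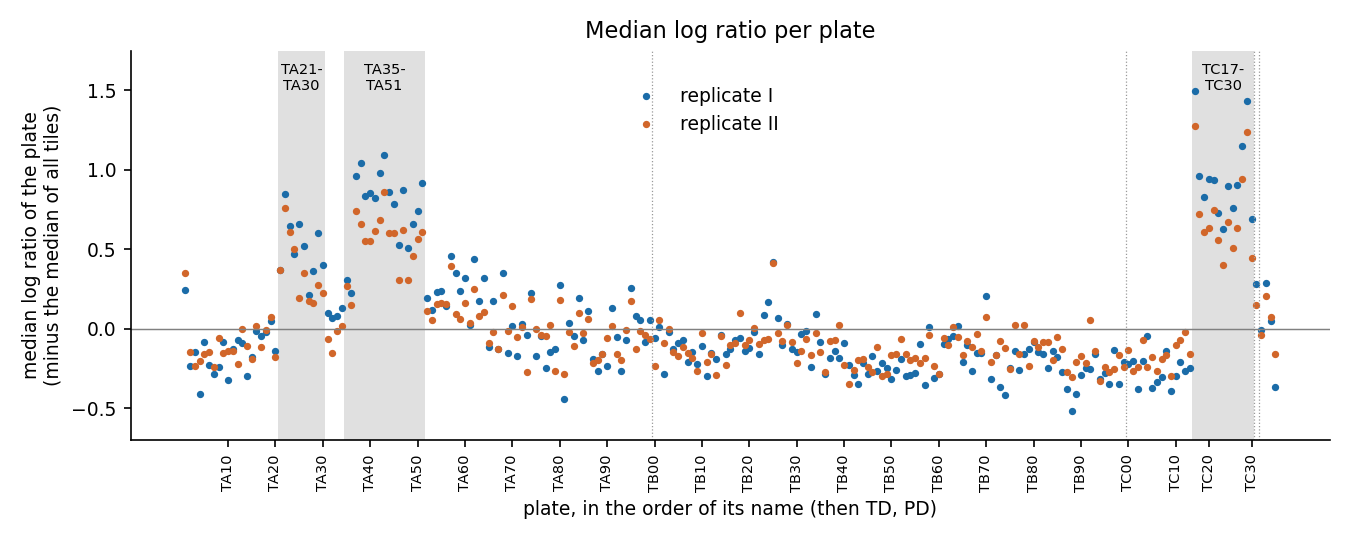
Median log ratio of the tiles of each plate (log base not stated), minus the median of all tiles, for replicate I and replicate II, with plates on the horizontal axis in the order of their names. Each point is 1 plate in 1 replicate, dotted lines part the sets, and grey bands mark TA21 to TA30, TA35 to TA51 and TC17 to TC30, where plate medians reached 1.499 in replicate I and 1.28 in replicate II at TC17.

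The stretches were runs of at least 5 consecutive plates with values, all called higher, and so were chosen after their values were seen. Plate TC26 had no values, so TC17 to TC30 spans a gap and holds 13 plates. When the values of all tiles were moved along the order of names, 2 of 21743 circular shifts gave TC17 to TC30 as large a difference in mean rank from the rest (two-sided permutation p = 9.2e-05, adjusted p = 0.000552 over 6 tests). The unshifted order counts among these shifts, and shifts 1 well apart overlap almost wholly, so they are not independent. A stretch picked for its high values is also bound to rank near the top. That p is therefore too small by an unknown amount and gives the stretch no support. With means over tiles, equal median absolute deviations, or only the plates outside the stretches as reference, the differences ranged from 0.370 to 0.501 for TA21 to TA30, from 0.620 to 0.743 for TA35 to TA51 and from 0.847 to 0.927 for TC17 to TC30. Of the 5 sets, none was called different from the rest in this test, with adjusted p-values from 0.525 for TB to 0.886 for PD. Sets TA and TB held 42.9% and 44.1% of the tiles, so the test could hardly find a difference there. Differences in median from the rest, averaged over replicates, ran from -0.298 for TB to 0.323 for TC.

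The second comparison was of IP with INPUT at single tiles. Of 21743 tiles, 1792 (8.24%) were higher and 844 (3.88%) lower than the median, so that 68.0% of the calls were higher (limma with Benjamini-Hochberg adjustment, adjusted p at most 0.05, n = 2). With the sign turned these are 1792 lower and 844 higher. The smallest called means were 0.75 and -0.75. The share called higher was 21.6% in TA21 to TA30, 40.2% in TA35 to TA51 and 53.5% in TC17 to TC30, against 2.08% (379 tiles) in the other plates. The stretches were picked for high plate medians on the same values, so a larger share inside them was fixed by that choice, and the shares only describe its size. By size alone, 615 tiles lay above 1 in both replicates, where 69.0 would if the replicates were unrelated, and 91 lay under -1 in both, where 11.9 would. Of the 615 tiles, 536 (87.2%) were in the 3 stretches.

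The number of calls moved with the setting. Scaling the replicates to the same median absolute deviation gave 51 tiles higher and 0 lower in limma. At an unadjusted p under 0.05 that setting had 3332 higher and 2380 lower tiles, against 3519 and 2598 as reported, and by the size rule 695 tiles lay above 1 in both replicates. Its prior degrees of freedom were 4.25, against 21.7. The counts by size moved too: 96 tiles lay above 1 and 57 under -1 in both replicates with plate means removed, and 5 and 11482 without centring, while centring on the mode left 56 under -1. Centring on the mode gave 1902 higher and 475 lower, values without centring gave 68 higher and 18973 lower, and centring on the mean of each plate gave 1 higher and 0 lower in limma, with 1935 and 1952 at an unadjusted p under 0.05. On simulated data with 200 changed tiles and independent noise, the test found 46.4% of changes of 1 and 0.57% of changes of 0.5. Of its calls, 13.7% and 45.0% were false on average, above the nominal 5%. The data gave far more calls than 200, and the difference between replicates was shared by next wells (r = 0.377). The simulated shares therefore do not carry over to the reported calls.

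Tile TB40E11 had the highest mean of all called tiles, 4.15 ± 0.386 (SD, n = 2, limma adjusted p = 1.265e-09), with 4.42 in replicate I and 3.87 in replicate II. Tile TB40D06 of the same plate came next at 3.38 ± 0.0162 (limma adjusted p = 2.575e-08). The lowest called means were -1.73 ± 0.291 for TA73H09 (limma adjusted p = 0.0001652) and -1.70 ± 0.180 for TB94F09 (limma adjusted p = 0.0001895). Both lower tiles had an adjusted p above 0.05 in limma when the replicates were scaled alike, although their means were still -1.73 and -1.70. With plate means removed they had -1.56 and -1.36 and TB40D06 had 3.39, and none of these 3 tiles was called. The prior degrees of freedom fell to 4.25 and 4.55 in these settings.

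The third comparison asked how far the replicates gave the same tiles. Across tiles, which are not independent, Pearson's r was 0.537 and Spearman's rho 0.489. Within the 3 stretches together r was 0.742, and in the other plates it was 0.359. By stretch it was 0.568 in TA21 to TA30, 0.755 in TA35 to TA51 and 0.787 in TC17 to TC30. The stretches were picked for plate medians called higher from both replicates, and their plates differ in level. Their larger r may come in part from that choice and only describes them. The medians of the 231 plates correlated at 0.952 (Spearman 0.833), and tiles within plates at 0.367. The top 5% of both replicates shared 604 of 1087 tiles (55.6%) and the bottom 5% shared 241 (22.2%), where chance gives 54.3. The difference between these shares was not tested, and with the sign turned they swap. Replicate I was spread 1.17 times as widely as replicate II, and the standard deviation of the difference between replicates was 0.564.

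**Figure D2:**
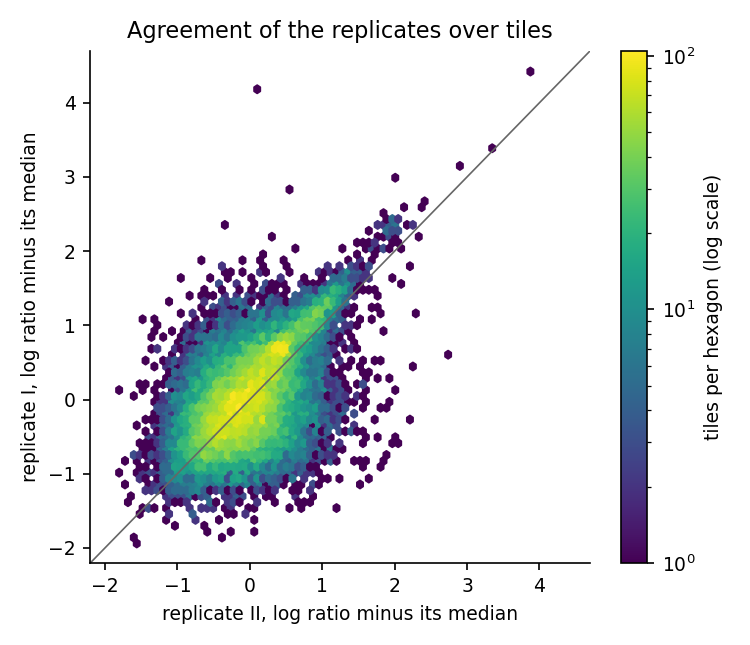
Log ratio minus the median (log base not stated) of each tile in replicate I against replicate II, as hexagons coloured by the number of tiles on a log scale, with the line of equal values. High tiles form a narrow band that lies mostly on the replicate I side of the line, low tiles form a broad cloud, and Pearson's r over all 21743 tiles was 0.537.

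The fourth comparison was of tiles with their neighbours in the order of names. Tiles called higher came in runs: 1409 of the 1792 (78.6%) stood in 277 runs of at least 2 consecutive wells, and 281.9 did so on average after shuffling. Of the tiles called lower, 321 of 844 (38.0%) stood in 141 runs, and 63.8 did so on average after shuffling. At an adjusted p of at most 0.01, 675 of 872 higher tiles (77.4%) and 20 of 174 lower tiles (11.5%) stood in runs. After shuffling, 68.4 and 2.88 did so on average. Fewer called tiles leave fewer in runs after shuffling too, so the shares at the 2 thresholds are not directly comparable. With equal median absolute deviations limma called 0 tiles lower (2380 at an unadjusted p under 0.05). At both thresholds the number of tiles in runs exceeded all 1000 shuffles, for higher and for lower calls (permutation p = 0.000999, the smallest they can give). The longest run of higher tiles had 53 wells, all in TC17, with a mean of 1.51 in replicate I and 1.27 in replicate II. A run of 52 wells in TC29 had 1.95 and 1.67, and a run of 19 wells at the start of TA01 had 1.91 and 1.55. These 3 runs were chosen after their values were seen.

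Stretches of nearly level values also occurred. In TC29, 21 consecutive wells had a mean of 2.11 ± 0.246 (SD of replicates, n = 2) with an SD between tiles of 0.0948, and a later stretch of 12 wells had 2.11 ± 0.258 with 0.0903. Of 72 tiles with a mean of at least 1.8, 41 were in TC25 to TC29 and 7 in TA01. Single tiles that stood far above both neighbours were rare. By at least 2, only 6 of 21565 tiles did so, 3 of them in TB40 (TB40E11, TB40D06 and TB40C07, the last chosen after its value of 3.01 was seen), and 0 tiles lay as far under both neighbours.

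**Figure D3:**
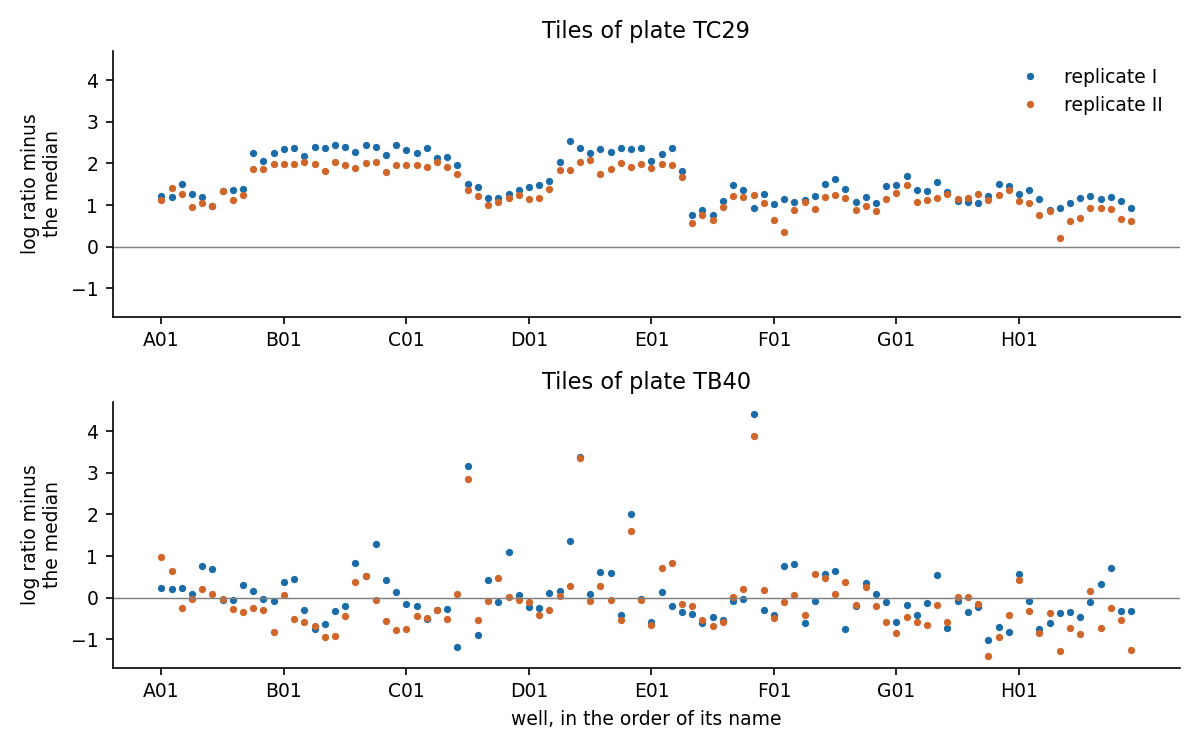
Log ratio minus the median (log base not stated) of each tile of plates TC29 (top) and TB40 (bottom) in replicates I and II, with wells in the order of their names. TC29 shows 2 level stretches of 21 and 12 wells near 2.11, and TB40 shows isolated high tiles that reach 4.42 in replicate I.

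The correlation between next wells was 0.592 in replicate I, 0.539 in replicate II and 0.394 between a well in one replicate and its neighbour in the other. It fell to 0.263 and 0.178 within replicates at 96 wells apart. The difference between the replicates was shared by next wells too (r = 0.377), and hardly by wells 12 apart (r = 0.0315). Shuffling removes this shared difference along with any shared signal, so the runs exceed what independent noise gives, which is a lower bar than noise shared by neighbours.

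**Figure D4:**
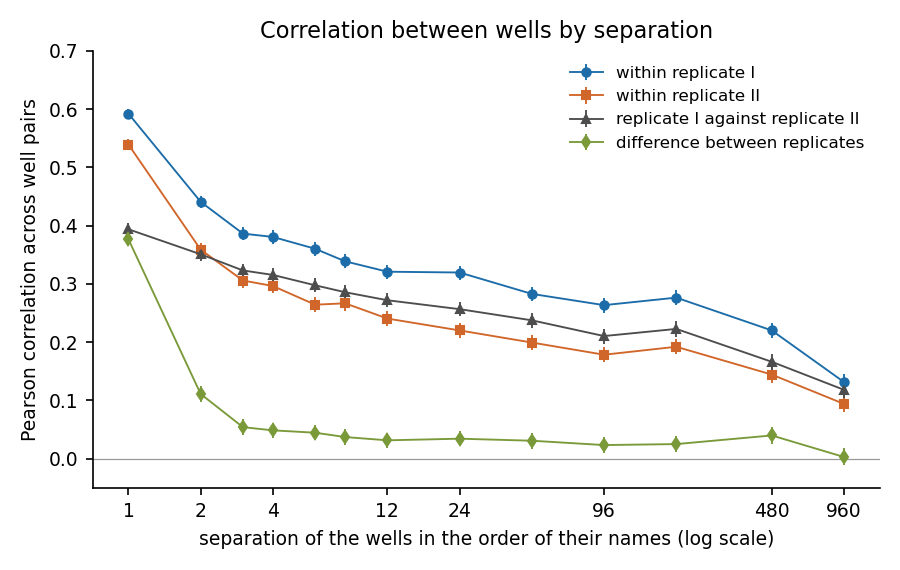
Pearson correlation across pairs of tiles (vertical axis) against how many wells apart they are in the order of names (horizontal axis, log scale), within replicate I, within replicate II, between the replicates and for the difference of the replicates, with 95% intervals that treat pairs as independent. The difference between replicates drops from 0.377 at 1 well to 0.111 at 2 wells, the curves within replicates I and II drop from 0.592 to 0.441 and from 0.539 to 0.359 over that step and more slowly after it, and the curve between replicates goes from 0.394 to 0.351.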

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

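Tests chosen only after the data were seen are all those of plates, of stretches of plates and of the correlation between next wells. The shift test of sets, level stretches of wells, single tiles and interleaved grids were also added then, and have no alternatives here. For the other results, the settings with plate means or medians removed, only sets TA and TB, or without the 3 stretches were chosen then. Of 98 alternatives for 18 results, 59 stayed alike. These kept a count within 1.5 times, a value within 1 SD of the replicates or a tile on its side of the threshold. At least 19 of the 59 could not have come out otherwise (single replicates of 2, and centring of a difference). The named tiles were also bound to stay called at a threshold of 0.01, with limma adjusted p-values of at most 0.0001895. Of the 98 alternatives, 34 moved further, 5 ended a call of a named tile and 0 reversed one. The differences of TA21 to TA30, TA35 to TA51 and TC17 to TC30 from the other tiles were 0.331 to 0.506, 0.567 to 0.802 and 0.745 to 0.982 in single replicates. Tiles called higher (1792) and lower (844) became 872 and 174 at an adjusted p of 0.01, 68 and 18973 with no centring, 1 and 0 with plate means removed, 51 and 0 with equal median absolute deviations, and 1056 and 472 with only sets TA and TB, with fewer tiles tested. Lower tiles became 475 with centring on the mode and 1549 with trend and robust prior, and the mixture called 78 higher, from 2262 (replicate I) and 98 (II). Unadjusted, limma had 2380 lower tiles with equal deviations and 1952 without plate means. All 51 and all 78 were among the 1792. Tiles above 1 in both replicates (615) became 96 with plate means removed and 5 with no centring; single replicates gave 932 to 1610, since 1 replicate then has to pass. Tiles under -1 in both (91) became 57 with plate means removed, 56 with the mode and 11482 with no centring, and 460 to 564 from single replicates. Plates higher (53) became 33 at 0.01 and 0 with no centring (limma, also 0 unadjusted). Plates lower (59) became 0 at 0.01 (78 unadjusted at 0.05), 10 with the mode, 228 with no centring, 100 with equal deviations and 98 with trend and robust prior. Runs became 151 (from 277) and 10 (from 141) at 0.01. The correlation between next wells, averaged over replicates (0.566; single replicates 0.539 to 0.592), was 0.395 with plate medians removed, and that of the replicates (0.537) was 0.367, or 0.359 without the 3 stretches. Without centring most values lie under 0, and a stricter threshold can only lower a count; for the other moved values the cause was not tested.

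Not run were the replicate as a random block, a dye term, arrays of 1 dye orientation and the filter on dye swaps, since the arrays of a swap held identical values, and the alternatives for genes, gene lists, classes, domains, superfamilies, gene bodies, GC content and gap length, since tile positions were not used here. No paired analysis was possible because there was 1 group. Signal over background could not be assessed from log ratios alone.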

Other observations

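Tests of neighbouring wells, of spot brightness and of spots with little DNA were chosen after the result was seen, and the tests of the difference between replicates were set before it. No biological explanation was tested, because the design has 1 group and tile positions were not used here.

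In plate TB58, the 24 wells in every other row from A and every other column from 2 on shared nearly 1 level, chosen for mention after their values were seen. Their median was 0.753 in replicate I (spread from quartiles 0.0305) and 0.434 in replicate II (0.0670), while the other 72 wells had -0.231 (0.533) and -0.230 (0.438). Each plate has 4 such interleaved grids of odd or even rows and columns, and of 911 grids with at least 12 wells on 228 plates, 4 had under 0.5 times the spread of the rest of their plate in both replicates: this one and 1 each in TA33, TC17 and TC29. The same grid of TA94 stood at 0.715 and 0.358, against -0.222 and -0.139 in its other wells, with a wider spread of 0.148 and 0.288. The grid was also high in TB26, at 0.528 and 0.397 against 0.00612 and -0.126, and in TA95, at 0.584 and 0.360 against 0.185 and 0.160, both with spreads like those of their other wells or wider. TA95 was picked after its values were seen, and this grid stood as high in TA33, at 0.307 and 0.320 against 0.0124 and -0.124. The grid exceeded the other wells by more than 0.3 in both replicates in 3 of 227 plates (TA94, TB26 and TB58). Of the other 3 grids only 1 did so, in TB19. Across the array outside that grid of TB58, 507 tiles (2.33%) lay within 0.1 of its level in both replicates, more than in any of the 8 equal squares around it (97 to 400 tiles), and 167 of them were in the 3 stretches of plates.

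Next wells had similar log ratios. If shared handling of a plate were the cause, the last well of a plate would resemble the first well of the next no more than wells 96 apart, but that correlation was 0.516 in replicate I against 0.263, and 0.499 against 0.178 in replicate II. If the place in the plate were the cause, touching wells 12 apart would be as alike as wells on either side of a row border, but the row border gave 0.599 against 0.326 (0.510 against 0.245 in replicate II). These tests address only the plate and the place in it, and where the spots lay on the slide was not examined. The order of names may follow something outside the plates, such as the order of tiles along chromosomes, which was not tested.

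The difference between replicates was shared by next wells (r = 0.377). Uneven signal over plates or print runs would carry over to wells 12 and 96 apart, where r was 0.0315 and 0.0234. A different spread of the replicates would vanish once the part linear in their mean was removed, and r was then 0.364. Where the spots lay on the slide was not examined here either. A candidate explanation that stays open is DNA that next tiles share, such as overlapping tiles or fragments longer than a tile, present in different amounts in the 2 preparations.

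The 3 stretches TA21 to TA30, TA35 to TA51 and TC17 to TC30 were high in both replicates. Log ratios with 13 or fewer decimals in both replicates made up 39.3% of tiles there and 3.01% elsewhere, which may mark bright spots if the values are differences of stored logs that lose a decimal from 10 upward. The stretches stood 0.751 above the other plates over all tiles. The difference was 0.463 among tiles short in neither replicate, 0.613 among those short in one and 0.496 among those short in both. Within the other plates, tiles short in both replicates had a median of 0.536, those short in one -0.104 and those short in neither -0.103. The marker thus went with the log ratio itself, so a split by it cannot separate brightness from the log ratio. It also has only 1 level, and brightness stays open. Spots with little DNA could be judged only by assuming that the level in TB58 is theirs, since DNA per spot was not measured. Under that assumption they were not the whole cause in TC17 to TC30, whose medians (0.942 and 0.713) lay above that level. The medians of TA35 to TA51 (0.755 and 0.532) lay close to it. Those of TA21 to TA30 (0.485 and 0.318) lay under it, as a mixture with other tiles would give. Of the tiles in TA21 to TA30 and TA35 to TA51 together, 13.9% (exact 95% interval 12.5 to 15.3) lay within 0.2 of it in both replicates. In TA21 to TA30 alone 10.8% did, in TA35 to TA51 15.6% and in TC17 to TC30 15.8%. Intervals of these shares treat tiles as independent, which neighbouring tiles are not, so they are likely too narrow. The grid in TA94 had 70.8% (48.9 to 87.4), and that in TB58, picked for its narrow spread, had 91.7%. The same grid was also high in TB26, TA95 and TA33, with wider spreads, and its shares there were not computed. These shares therefore do not exclude spots with little DNA at other levels. Regions rich in repeats or heterochromatin, where level values over many wells could come from repeated sequence, stay open and untested.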
